A study of Arabis alpina with 12 samples.

How the data were processed

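The analysis used the deposited table of normalized counts of 19722 genes in 12 libraries and the 4 deposited comparison tables of genes the authors listed as changed. Libraries were 150 bp single-end reads of polyA RNA (1 µg, RIN above 8), and per the submitters' processing notes HISAT2, StringTie, TopHat and DESeq2 were used. Their versions, settings and order, and the genome build, are not given in the sources used here. Plants had grown for 8 weeks in days of 16 h light at 20 °C and 8 h dark at 18 °C before vernalization.

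The signal values are normalized counts, which per the file headers the authors deposited as counts, after gene counts had been divided by 1 factor per library. Each library's values were whole multiples of 1 step, so whole reads were recovered, and 100% of the values lay within 0.05 of a whole number. In V2 replicate 2 at both times that step is close to 1, so that the recovery rests on the smallest value of the column. The authors made FPKM per library and group for 3877 of the 3884 genes listed in at least 1 comparison. The authors computed log2 fold changes and deposited those with an absolute value above 1. The authors adjusted p-values with the Benjamini-Hochberg method. The authors counted 30690 predicted transcripts, 18720 homologues, and 2118, 4682, 4005 and 3671 transcripts at adjusted p under 0.05 in the comparisons in order. Every per-sample column was used, and per-sample columns used for no sample numbered 0. In 1 gene of the comparison at 5 d FPKM cells are displaced, and the FPKM of that table was not used for it.

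The design written before the data were examined had named an edgeR test on raw counts. Since the files held normalized counts, limma with an intensity trend was run on log2(normalized count + 1), with 1 mean per group and all 12 libraries in 1 fit. Genes needed a mean normalized count of at least 10 and at least 2 usable libraries in each group compared. P-values were adjusted over the genes of each comparison with the Benjamini-Hochberg method, and a gene was called under 0.05. The interaction is the change over time in V3 minus that in V2. R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0 were used.

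Zeros that other values contradict were treated as failed measurements. Where FPKM was given, a 0 was failed if its FPKM was at least 1, or if the FPKM times the gene's usual count per FPKM gave an expected count of at least 20. Where no FPKM was given, a 0 was failed if another library of its group held at least 20. In all, 17431 values were failed, 5356 by FPKM and 12075 by partner libraries, while 154 discordant zeros with low FPKM were kept. No failed zero occurred in 10978 genes. This rule was chosen and revised 3 times after the values had been seen, and its earlier versions were kept as alternatives. The partner rule removes low values only, the FPKM rule can leave only zeros, and both may understate spread. The share of genes at 0 where both partners held at least 20 was 34% in V2 0 d replicate 3 and 1.47% to 2.78% in the others, and the 10 most abundant genes held 2.69% to 5.34% of each library.

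Gene lists were fixed by A. thaliana locus before the data were examined, except that ribosomal proteins and histones were found by annotation text. Homologues are given for 2896 and symbols for 1633 of the 3884 listed genes, and a member could be paired through these alone. The fixed and paired loci numbered 15 and 9 for dormancy, 17 and 5 for sugar starvation, 12 and 1 for abscisic acid metabolism, 18 and 8 for abscisic acid response, 22 and 3 for auxin synthesis and transport, 20 and 5 for auxin response, 21 and 6 for cytokinin metabolism, 10 and 1 for type-A response regulators, 10 and 0 for strigolactone, 23 and 7 for gibberellin, 16 and 9 for S phase, 21 and 13 for G2/M, 13 and 4 for flowering repressors, 17 and 4 for flowering promoters, 11 and 2 for floral organ identity, 24 and 6 for meristem and boundary, 22 and 7 for cold response, 8 and 3 for heat shock, 27 and 8 for wall loosening, 18 and 6 for circadian clock, 13 and 5 for flavonoid, 13 and 5 for jasmonate and defence, 32 and 5 for photosynthetic markers, 18 and 4 for vascular markers and 6 and 2 for senescing-leaf markers, and 35 ribosomal protein and 11 histone genes were found. Lists of at least 3 tested members were tested by camera against other tested genes with a homologue. It used signed limma statistics, a preset correlation of 0.01 and adjustment per comparison. They were retested with an estimated correlation and fry. Members were also adjusted over the list alone. BRC1, FLC, DRM1, SOC1 and CYCD3;1 had no paired gene and are not analysed here.

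Genes were named by a rule fixed before the data were examined. It took NCED3 among the genes always named, the 5 largest changes per direction among called genes with a mean of at least 5 CPM, no overlap between groups and a symbol, up to 4 called members of each list with the smallest adjusted p, and up to 2 uncalled members with the largest fold change. The overlap criterion was not used for the interaction. After the data had been seen, genes whose ratio of count to FPKM ranged more than 2-fold were passed over among the largest changes, which removed 1 gene. Not every gene the rule gave is printed.

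A self-test changed 200 genes in 1 group of simulated counts that kept each gene's mean, the trend of spread and the failed zeros, 2-fold or 4-fold in either direction. Of genes changed 2-fold, limma recovered 29.3%, 38%, 33%, 46% and 10% in the comparisons in the order zones at 0 d, zones at 5 d, time in V2, time in V3 and interaction, and of those changed 4-fold 92.9%, 89%, 95%, 89.9% and 68%. False calls made up 8.33%, 4.51%, 7.25%, 4.25% and 3.7% of its calls, those of edgeR 6.67%, 6.67%, 6.25%, 2.35% and 1.96% and those of DESeq2 21.9%, 17%, 12.4%, 15% and 25.6%. camera found a list raised 2-fold each time, and 2, 1, 0, 1 and 3 of 100 unchanged lists passed a threshold of 0.05. The simulated genes varied independently of each other. The self-test therefore does not show how camera treats lists whose members vary together.

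Of the authors' listed genes, 542 of 1128, 1718 of 1984, 1061 of 1757 and 1428 of 1767 were tested. Of those, 258, 1624, 935 and 1315 were called in the listed direction, none oppositely. Not called were 284, 94, 126 and 113. Others had failed zeros or low counts. Alternatives changed the test, the scale, the filter, the treatment of zeros, the pseudocount (5), the threshold (absolute log2 fold change of at least 1), the unit (FPKM), and left out each library in turn. A result was counted as moved at a change of 1.5-fold. Gene families were taken from annotation text in 26 fixed groups, 22 of which were tested with Fisher's exact test against the other genes with a homologue. No reads, alignment or genome sequence were analysed here.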

Results

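Messenger RNA was sequenced from lateral buds of Arabis alpina (ecotype Pajares), a perennial relative of Arabidopsis thaliana, in 12 libraries. Buds were taken from the dormant zone (V2) or the growing zone (V3) of plants vernalized for 12 weeks at 4 °C, either at the end of the cold (0 d) or after 5 days back in long days (5 d). Each of the 4 groups held 3 libraries, which the labels describe as biological replicates. The reads recovered came to 22168999, 20654283 and 12252622 in V2 and 21204647, 21144939 and 22415522 in V3 at 0 d. At 5 d they came to 18377958, 20967811 and 22581638 in V2 and 21955093, 20216921 and 22586938 in V3.

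Gene values are given as mean ± SD of normalized counts over 3 libraries, or over the n printed beside them. Many zeros in the table did not reflect absent transcript: of 1539 zeros in listed genes whose partner libraries held counts, 80.8% had an FPKM of at least 1. Such failed zeros were left out library by library, 6553 of them in V2 0 d replicate 3 and 890 to 1228 in each other library. Fold changes are log2 differences of normalized count + 1, a scale that understates the changes of low genes. A group listed at 0 in every usable library adds no spread to the fit. The adjusted p of such a gene can therefore be too low. Genes were called by limma at an adjusted p under 0.05. Gene names come from the A. thaliana homologues given for the genes the authors listed as changed. Every list member was therefore chosen on these same libraries. Neither the share of a list that was called nor a list test is independent evidence. HIS1-3 is in the dormancy and histone lists, NAP in the dormancy and senescing-leaf lists, and NCED3 in the dormancy and abscisic acid metabolism lists. Counts of higher and lower genes adjusted over the list alone are given where they differed in lists of at least 2 genes tested. Where leaving out 1 library ended calls of list members, the lowest number still called is given as lowest. A gene with 2 usable libraries in a compared group was not tested without either library, and its call counts as ended.

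**Figure D1:**
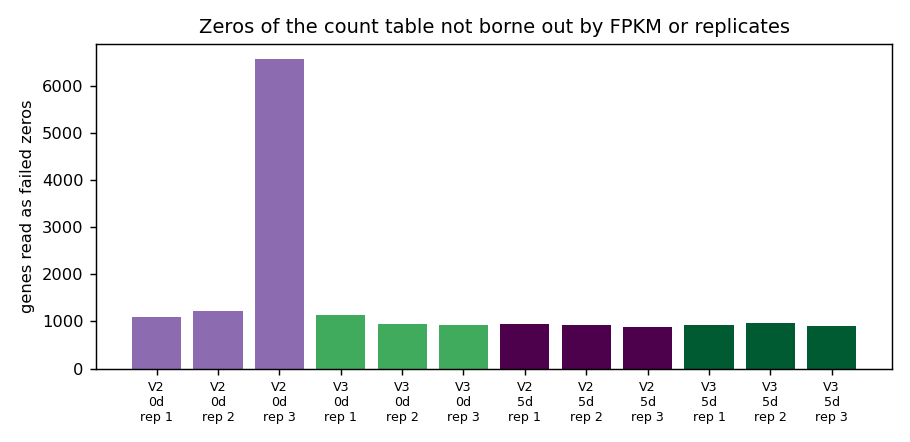
Failed zeros, meaning zeros that FPKM or partner libraries contradict, as the number of genes in each of the 12 libraries (bars). V2 0 d replicate 3 held 6553 and the other libraries 890 to 1228.

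The first principal component of 9990 genes without a missing value held 38.1% of the variance and set 0 d apart from 5 d in every library, and the second held 27.6%. V3 0 d replicate 1 lay at 86.5 on the first component, against 40.3 and 56.1 for its partners, and had the largest mean distance to its own group, 0.874. It differed from its partners in the gene groups that separate the zones. Its S phase genes averaged 1.03 relative to the mean of all libraries on the log2 scale, against 0.176 and 0.473 in replicates 2 and 3, and its ribosomal protein genes 0.88 against 0.232 and 0.373. Its abscisic acid response genes averaged -2.21, against -0.028 and -0.475, and its dormancy genes -1.56, against 0.271 and -0.757. Vascular markers averaged -3.42 in that library, -1.39 to -2.37 in the others at 0 d, and 1.06 to 2.31 in V2 and 3.48 to 3.86 in V3 at 5 d. Photosynthetic markers averaged -2.19 in that library, 0.003 and -0.319 in its partners, and 0.896 to 0.999 in V3 at 5 d.

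**Figure D2:**
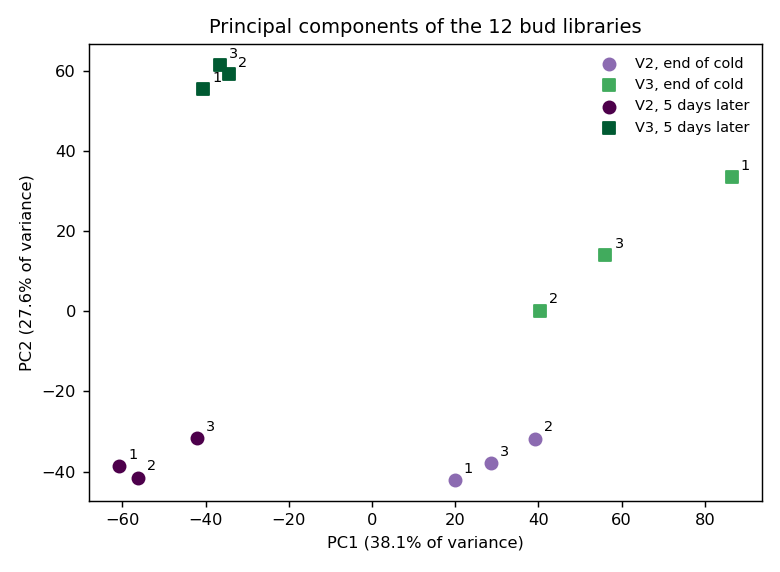
First and second principal components of log2 normalized counts of 9990 genes, with the share of variance on each axis; each point is a library. The first component (38.1%) separated 0 d from 5 d, and V3 0 d replicate 1 lay farthest out at 86.5.

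Buds of both zones were compared at the end of the cold to ask what set them apart. Of 16525 genes tested, limma called 722, 186 higher and 536 lower in V3, and 458 of them differed at least 2-fold. With zeros as deposited the balance of 186 to 536 turned, to 301 higher and 276 lower with limma and 250 and 144 with edgeR. Dormancy and abscisic acid response genes were among those lower in growing-zone buds, and genes of DNA replication and mitosis were among those higher. Most members of every large list were not called, and no list passed with an estimated correlation (lowest adjusted p = 0.399).

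Of the 8 abscisic acid response genes, 3 were lower in V3 and none was higher, with 5 not called (lowest 1, 0 and 8 adjusted over the list alone, median log2 fold change -1.53, camera adjusted p = 0.0114, adjusted p = 0.467 with an estimated correlation). ABI1, a phosphatase that restrains abscisic acid signalling, stood at 409 ± 107 against 858 ± 148 (log2 fold change -1.08, adjusted p = 0.0104). RD29B and RAB18, late markers of that signalling, were not called at log2 fold changes of -4.39 and -3.07. 2 of 9 BRC1 and dormancy genes were lower and none higher (lowest 0, 0 and 6 adjusted over the list alone, median log2 fold change -1.90, camera adjusted p = 0.0597). 1 of 5 sugar starvation genes was lower and none higher (lowest 0, 0 and 3 adjusted over the list alone, median -0.65, camera adjusted p = 0.113). HB21, a homeobox gene that acts below BRC1 in A. thaliana buds, had 33.8 and 24.1 (adjusted p = 0.00721) in V2 and was listed at 0 in V3, where its FPKM was 0, 0.509 and 0. NAP, a NAC factor of leaf senescence, stood at 7.36 ± 12.8 against 141 ± 47.5 (log2 fold change -5.59, adjusted p = 0.0157, but 0.0652, 0.0532 and 0.0527 without V2 0 d replicate 1 and V3 0 d replicates 1 and 3). NCED3, which encodes the rate-limiting enzyme of abscisic acid synthesis and was the 1 metabolism gene measured, was not called at 348 ± 321 against 1450.03 ± 644 (log2 fold change -2.42, adjusted p = 0.0557). BCAT2, a transaminase of the sugar starvation list, had 255, 209 and 157 (adjusted p = 3.74e-05) in V2 and was listed at 0 in 2 usable V3 libraries (FPKM 0.0794 and 0.849, left out 2.32).

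Of the 9 S phase genes, 2 were higher in V3 and none was lower, with 7 not called (lowest 0, 6 and 0 adjusted over the list alone, median log2 fold change 0.69, camera adjusted p = 0.000197, adjusted p = 0.399 with an estimated correlation). MCM5, a subunit of the replicative helicase, stood at 4821 ± 927 against 2702 ± 109 (log2 fold change 0.82, adjusted p = 0.0287, but up to 0.0904 without 4 single libraries in turn). Of the 12 G2/M genes, 2 were higher in V3 and none was lower, with 10 not called (lowest 0, 7 and 0 adjusted over the list alone, median log2 fold change 0.74, camera adjusted p = 4.2e-05, adjusted p = 0.399 with an estimated correlation). CYCA1;1, a mitotic cyclin, stood at 1894 ± 609 against 1076 ± 107 (log2 fold change 0.77, adjusted p = 0.0453, but 0.109 and 0.121 without V2 0 d replicates 1 and 3). Of the 10 histone genes, 2 were higher in V3 and none was lower, with 8 not called (lowest 0, 9 and 1 adjusted over the list alone, median log2 fold change 0.77, camera adjusted p = 0.00028, adjusted p = 0.399 with an estimated correlation). The member of opposite sign was HIS1-3, a drought-induced linker histone (log2 fold change -2.49). Of the 30 ribosomal protein genes, 1 was higher in V3 and none was lower, with 29 not called (lowest 0, 13 and 1 adjusted over the list alone, median log2 fold change 0.48, camera adjusted p = 1.7e-05, adjusted p = 0.399 with an estimated correlation). In these 5 lists, and in some that did not pass, V3 and V2 library means did not overlap.

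1 of 3 flowering repressors was lower and none higher (lowest 0, 0 and 2 adjusted over the list alone, median log2 fold change -0.54, camera adjusted p = 0.407). None of 4 flowering promoters was called (median 0.50, camera adjusted p = 0.18). 2 of 7 cold response genes were lower and none higher (lowest 0, 0 and 4 adjusted over the list alone, median -1.003, camera adjusted p = 0.23). SMZ, an AP2-type repressor of flowering, had 18.3 and 54.4 (adjusted p = 0.00187) in V2 and was listed at 0 in V3. SVP and TFL1, which also hold back flowering, were not called (log2 fold changes -0.54 and 0.13). The galactinol synthase GOLS3 of cold acclimation stood at 203 ± 141 (n = 2) against 654 ± 154 (log2 fold change -1.85, adjusted p = 0.0442, but 0.1, 0.113 and 0.0599 without V2 0 d replicates 1 and 3 and V3 0 d replicate 1). 2 of 5 jasmonate and defence genes were higher in V3 and 1 lower (lowest 1, 2 and 3 adjusted over the list alone, median log2 fold change -0.74, mean -0.05, test direction higher, camera adjusted p = 0.853). None of 7 gibberellin genes was called (0 and 3 adjusted over the list alone, median -0.52, camera adjusted p = 0.407). 1 of 5 cytokinin metabolism genes was higher in V3 and none lower (lowest 0, 1 and 1 adjusted over the list alone, median -0.08, mean 0.01, test direction higher, camera adjusted p = 0.554). LOX2, a plastid lipoxygenase of jasmonate synthesis, stood at 1829.7 ± 1168 (n = 2) against 346 ± 45.1 (log2 fold change 2.24, adjusted p = 0.0287, but 0.0877 and 0.0839 without V2 0 d replicates 1 and 3), and JAZ10, a repressor of that pathway, at 431 ± 88.1 against 1007 ± 129 (log2 fold change -1.23, adjusted p = 0.00791). 1 of 3 auxin synthesis and transport genes was higher in V3 and none lower (lowest 0, median log2 fold change 0, mean 0.16, test direction higher, camera adjusted p = 0.407). 1 of 4 auxin response genes was lower and none higher (lowest 0, median -0.50, camera adjusted p = 0.649). None of 6 meristem and boundary genes was called (median -0.09, mean 0.02, test direction higher, camera adjusted p = 0.595). 1 of 8 wall loosening genes was lower and none higher (lowest 0, 0 and 2 adjusted over the list alone, median log2 fold change -0.14, mean -1.17, test direction higher, camera adjusted p = 0.853). None of 6 clock genes was called (median -0.19, mean -0.32, test direction higher, camera adjusted p = 0.853). None of 4 flavonoid genes was called (0 and 3 adjusted over the list alone, median -0.58, camera adjusted p = 0.405). None of 4 vascular markers was called (0 and 1 adjusted over the list alone, median log2 fold change 0.11, mean -0.54, test direction higher, camera adjusted p = 0.808). 1 of 2 senescing-leaf markers was lower and none higher (lowest 0, 0 and 2 adjusted over the list alone). The floral organ identity genes CRC and UFO, 2 heat shock genes, 2 photosynthetic markers and the type-A regulator ARR4 (log2 fold change 0.76) were not called.

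Outside the lists, PLC1, a phospholipase C of inositol signalling, had 529 and 241 (adjusted p = 2.16e-06) in V2 and was listed at 0 in the usable V3 libraries (FPKM 0.0568, 1.87 and 0.304). DDF1, an AP2 factor that lowers gibberellin under stress, stood at 17.3 ± 13.1 against 234 ± 139 (log2 fold change -3.79, adjusted p = 0.00434). The number called depended on single libraries. It was 191 and 302 without V2 0 d replicates 1 and 3. It was 343, 1745 and 358 without V3 0 d replicates 1, 2 (near V2) and 3. Of the 30 named calls, 25, 8 and 21 ended without V2 0 d replicates 1, 2 and 3, and 19, 2 and 22 without V3 0 d replicates 1, 2 and 3.

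The same comparison at 5 d asked how far the zones had moved apart. Of 17271 genes tested, limma called 6232 (2802 higher and 3430 lower in V3), of which 2527 differed at least 2-fold. By camera, the dormancy, abscisic acid response, sugar starvation, cold, clock and gibberellin lists were lower in growing-zone buds, and the cell-cycle, histone and ribosomal protein lists higher. All of these calls were lost with an estimated correlation (adjusted p = 0.211 to 0.225). TFL1 was lower in V3, and the carpel gene CRC was higher.

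Of the 9 BRC1 and dormancy genes, 9 were lower in V3 and none was higher (lowest 7, median log2 fold change -3.47, camera adjusted p = 0.00623, adjusted p = 0.211 with an estimated correlation). HB53, of the homeobox group downstream of BRC1, stood at 85.6 ± 9.42 against 2298 ± 569 (log2 fold change -4.71, adjusted p = 0.000223), and the dormancy-associated gene DRMH1 at 70.9 ± 47.8 against 3827 ± 889.5 (log2 fold change -5.97, adjusted p = 0.000909). HB21 and NAP were listed at 0 in V3, with 13.7, 126 and 67.4 (adjusted p = 0.000413) and 158, 183 and 98.8 (adjusted p = 0.000813) in V2. NCED3, again the 1 metabolism gene, stood at 184 ± 61.7 against 2031 ± 489 (log2 fold change -3.47, adjusted p = 0.0025). Of the 8 abscisic acid response genes, 8 were lower in V3 and none was higher (lowest 5, median log2 fold change -2.07, camera adjusted p = 0.00623, adjusted p = 0.211 with an estimated correlation). ABI5, a bZIP factor that activates the response, stood at 32 ± 16.8 against 502 ± 138 (log2 fold change -4.05, adjusted p = 0.000154), and ABI1, which restrains it, at 429 ± 30.7 against 2591 ± 187 (log2 fold change -2.59, adjusted p = 1.6e-05). Of the 4 sugar starvation genes, 4 were lower in V3 and none was higher (median log2 fold change -2.49, camera adjusted p = 0.00623, adjusted p = 0.211 with an estimated correlation). TPS9, a trehalose phosphate synthase-like gene that sugar represses, stood at 1052 ± 182 against 5142 ± 680.3 (log2 fold change -2.29, adjusted p = 1.23e-05), and BZIP1, a regulator of the low-energy response, at 50.8 ± 12.1 against 413 ± 24.2 (log2 fold change -3.02, adjusted p = 3.58e-05).

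**Figure D3:**
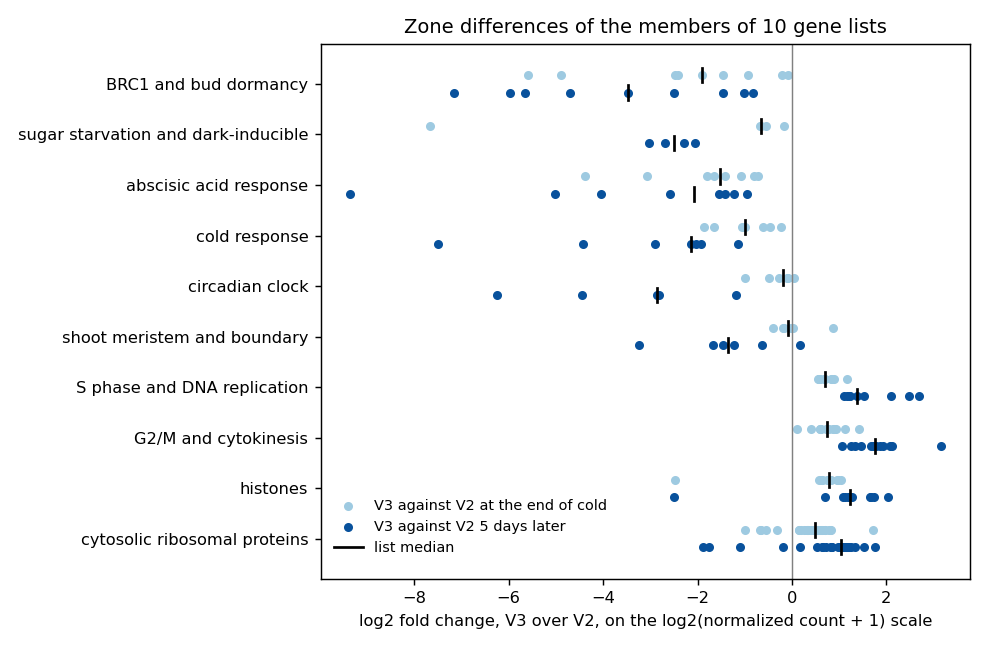
Log2 fold change, V3 over V2, of each member of selected gene lists at 0 d and 5 d, with medians. At 5 d, 9 of 9 dormancy genes were lower and 12 of 12 G2/M genes higher in V3.

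Of the 9 S phase genes, 9 were higher in V3 and none was lower (lowest 8, median log2 fold change 1.38, camera adjusted p = 0.00258, adjusted p = 0.211 with an estimated correlation). CDT1A, a replication licensing factor, stood at 1711 ± 628 against 382 ± 45.3 (log2 fold change 2.104, adjusted p = 0.000307). Of the 12 G2/M genes, 12 were higher in V3 and none was lower (lowest 9, median log2 fold change 1.75, camera adjusted p = 0.00033, adjusted p = 0.211 with an estimated correlation). AUR1, a mitotic kinase, stood at 1189 ± 49.3 against 291 ± 130 (log2 fold change 2.12, adjusted p = 0.000266), and CYCA1;1 at 2128 ± 184 against 583 ± 3.2 (log2 fold change 1.86, adjusted p = 0.000132). Of the 10 histone genes, 8 were higher in V3 and 1 lower, with 1 not called (median log2 fold change 1.22, camera adjusted p = 0.00623, adjusted p = 0.211 with an estimated correlation). HTA6, a histone gene, stood at 6693 ± 179.9 against 1675 ± 442 (log2 fold change 2.03, adjusted p = 0.000285). The member that was lower was again HIS1-3. Of the 30 ribosomal protein genes, 21 were higher in V3 and 2 lower, with 7 not called (lowest 21, 23 and 2 adjusted over the list alone, median log2 fold change 1.05, camera adjusted p = 0.00033, adjusted p = 0.225 with an estimated correlation). RPL12C, of the large subunit, stood at 2348 ± 138 against 1063 ± 102 (log2 fold change 1.15, adjusted p = 0.000938).

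Of the 7 gibberellin genes, 1 was higher in V3 and 6 lower (lowest 6, median log2 fold change -1.73, camera adjusted p = 0.0413, adjusted p = 0.211 with an estimated correlation). The genes lower in V3 acted in opposite ways: GA2OX2, which deactivates gibberellin, stood at 439 ± 31.7 against 7372 ± 800.2 (log2 fold change -4.06, adjusted p = 0.000504) and the receptor GID1B at 231 ± 128 against 1396 ± 472 (log2 fold change -2.68, adjusted p = 0.000873). The gene higher in V3 was RGL1, a DELLA repressor, at 149 ± 15.6 against 69.6 ± 10.6 (log2 fold change 1.09, adjusted p = 0.00187). That list's adjusted p was 0.118 and 0.142 without V2 5 d replicates 1 and 3. 3 of 3 auxin synthesis and transport genes were higher in V3 and none lower (lowest 1, median log2 fold change 1.17, camera adjusted p = 0.0816). 1 of 5 auxin response genes was lower and none higher (median 0.30, mean 0.28, test direction lower, camera adjusted p = 0.982). 1 of 4 cytokinin metabolism genes was higher in V3 and 1 lower (2 and 2 adjusted over the list alone, median -0.52, camera adjusted p = 0.988). PIN6, an auxin carrier, stood at 880.3 ± 45 against 402 ± 113 (log2 fold change 1.17, adjusted p = 0.00234), and GH3.6, which conjugates auxin, at 3049 ± 188 against 9959 ± 845 (log2 fold change -1.71, adjusted p = 3.88e-06). Both called cytokinin genes encode enzymes that degrade it, CKX1 at 238 ± 10.7 against 1326 ± 425 (log2 fold change -2.43, adjusted p = 0.00136) and CKX5 at 209 ± 52 against 67.6 ± 12.3 (log2 fold change 1.60, adjusted p = 0.00814). ARR4, the 1 type-A response regulator, was higher at 918 ± 15.7 against 173 ± 51.5 (log2 fold change 2.45, adjusted p = 0.00043).

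Both flowering repressors measured were lower in V3. TFL1, which keeps shoot meristems indeterminate, stood at 444 ± 76.1 against 2769 ± 236 (log2 fold change -2.65, adjusted p = 8.42e-06), and SVP, a MADS repressor, at 2028 ± 299.9 against 5613 ± 795 (log2 fold change -1.47, adjusted p = 0.000266). 1 of 4 flowering promoters was higher in V3 and none lower (2 and 0 adjusted over the list alone, median log2 fold change 0.67, camera adjusted p = 0.251). 4 of 6 meristem and boundary genes were lower and none higher (0 and 5 adjusted over the list alone, median -1.35, camera adjusted p = 0.0551). AGL19, a MADS promoter of flowering, stood at 428 ± 5.89 against 196 ± 10 (log2 fold change 1.13, adjusted p = 0.0071), and RAX2, a MYB gene of axillary meristem formation, at 18.4 ± 5.87 against 179 ± 42.9 (log2 fold change -3.23, adjusted p = 0.000299). Of the 2 floral organ identity genes, CRC stood at 69.6 ± 17.9 against 2.71 ± 2.4 (log2 fold change 4.55, adjusted p = 0.00108) and UFO, a cofactor of LEAFY, at 70.9 ± 22 against 316 ± 43.4 (log2 fold change -2.18, adjusted p = 0.000242). Of the 7 cold response genes, 7 were lower in V3 and none was higher (lowest 5, median log2 fold change -2.13, camera adjusted p = 0.00708, adjusted p = 0.211 with an estimated correlation). COR28, a gene linking cold and the clock, stood at 7.23 ± 4.93 (n = 2) against 161 ± 37.6 (log2 fold change -4.42, adjusted p = 0.00021), and GOLS3 was listed at 0 in V3 with 211, 185 and 149 (adjusted p = 3.81e-06) in V2. Of the 5 clock genes, 5 were lower in V3 and none was higher (median log2 fold change -2.85, camera adjusted p = 0.0202, adjusted p = 0.211 with an estimated correlation). ELF4, of the evening complex, stood at 10.7 ± 6.37 against 238 ± 55.4 (log2 fold change -4.46, adjusted p = 0.000154). In the 10 lists that passed camera, and in most that did not, V3 and V2 library means did not overlap.

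2 of 5 jasmonate and defence genes were higher in V3 and 1 lower (lowest 2, median log2 fold change 0.32, camera adjusted p = 0.251). 4 of 8 wall loosening genes were higher in V3 and none lower (lowest 1, median 1.03, camera adjusted p = 0.176). None of 5 flavonoid genes was called (median log2 fold change 0.29, mean -1.38, test direction higher, camera adjusted p = 0.968). LOX2 stood at 61436 ± 5706 against 4747 ± 1923 (log2 fold change 3.79, adjusted p = 0.000311), and EXPA10, an expansin, at 2879 ± 174 against 1015 ± 65.2 (log2 fold change 1.503, adjusted p = 0.00205). 2 of 3 vascular markers were higher in V3 and none lower (lowest 1, median log2 fold change 2.102, camera adjusted p = 0.193). 2 of 4 photosynthetic markers were higher in V3 and none lower (lowest 1, median 0.81, camera adjusted p = 0.196). 1 of 2 senescing-leaf markers was lower and none higher. 1 of 2 heat shock genes was lower and none higher (lowest 0, 0 and 2 adjusted over the list alone). XCP1, a protease of dying vessels, stood at 297 ± 29 against 71.8 ± 41.1 (log2 fold change 2.23, adjusted p = 0.00214). Outside the lists, ATSDI1, a sulphur-deficiency gene, had 2616, 1409.9 and 2889 (adjusted p = 6.49e-09) in V3 and was listed at 0 in V2 (FPKM 0, 0 and 0.0823). KAT2, a potassium channel of guard cells, had 602, 609 and 719.8 (adjusted p = 1.38e-11) in V3 and was likewise listed at 0 in V2. CP2, a cysteine protease, stood at 9719 ± 107 against 199 ± 69.5 (log2 fold change 5.67, adjusted p = 2.58e-05), and DREB2A, a drought and heat factor, at 12.2 ± 9.97 against 695 ± 138 (log2 fold change -6.00, adjusted p = 4.69e-05).

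**Figure D4:**
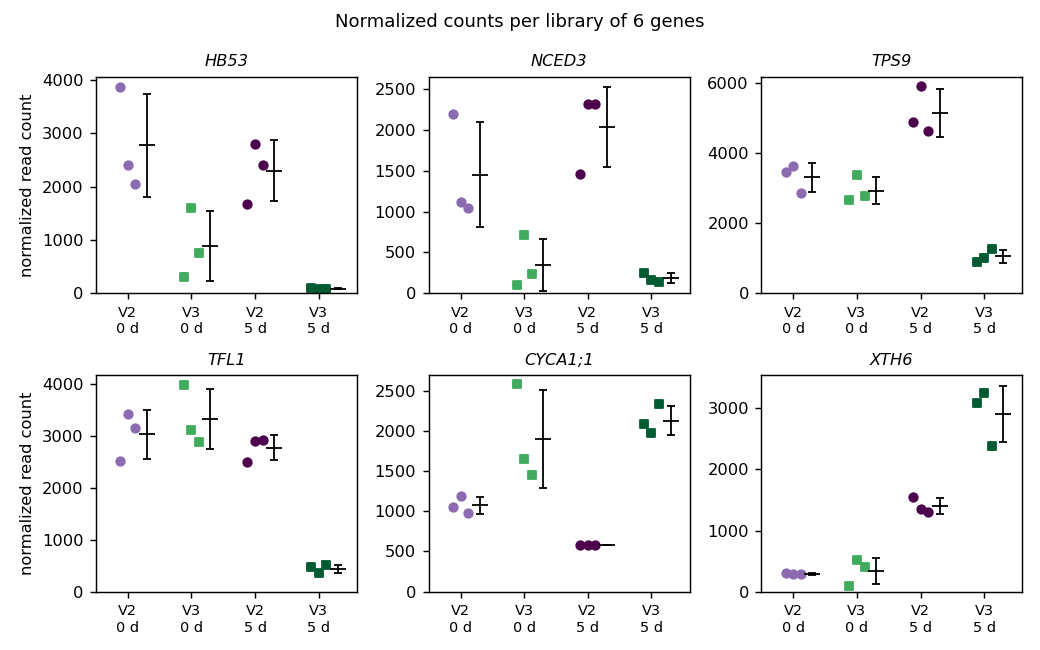
Normalized counts of HB53, NCED3, TPS9, TFL1, CYCA1;1 and XTH6 in each library (points) with mean ± SD of each of the 4 groups of 3 libraries. At 5 d the mean of HB53 was 85.6 in V3 and 2298 in V2.

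Of the 78 named calls at 5 d, 9, 5 and 10 ended without V2 5 d replicates 1, 2 and 3, and 6, 8 and 9 without V3 5 d replicates 1, 2 and 3. A gene called at 5 d and not at 0 d is not thereby shown to differ between the times, which the interaction tested. Of the genes tested at both times, 123 were higher in V3 at 0 d and at 5 d, where independence would give 29.3, and 264 were lower at both, where it would give 99.5. Another 19 were called in opposite directions, and the fold changes of all genes correlated at r = 0.338. Without single libraries the 387 genes shared became 91 (V2 0 d replicate 1) to 1124 (V3 0 d replicate 2).

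The dormant-zone buds were compared between 5 d and 0 d to ask how they respond to warmth. Of 16580 genes tested, limma called 3956, with 2084 rising and 1872 falling, and 1549 changed at least 2-fold. By camera the ribosomal protein, S phase and G2/M lists fell, which was lost with an estimated correlation (adjusted p = 0.615 to 0.732), and the heat shock factor HSFA2 fell. BZIP1, LOX2 and XCP1 rose, while most dormancy and abscisic acid response genes were not called.

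Of the 31 ribosomal protein genes, 1 rose and 21 fell, with 9 not called (lowest 15, 1 and 23 adjusted over the list alone, median log2 fold change -0.97, camera adjusted p = 6.71e-08, adjusted p = 0.615 with an estimated correlation). RS27A fell from 5966 ± 476 to 2304 ± 499 (log2 fold change -1.39, adjusted p = 0.000769). Of the 9 S phase genes, 3 fell and none rose, with 6 not called (lowest 1, median log2 fold change -0.73, camera adjusted p = 0.0104, adjusted p = 0.732 with an estimated correlation). MCM4, a helicase subunit, fell from 3011 ± 169.5 to 1817 ± 72.1 (log2 fold change -0.73, adjusted p = 0.00988). Of the 12 G2/M genes, 5 fell and none rose, with 7 not called (lowest 3, 0 and 10 adjusted over the list alone, median log2 fold change -0.99, camera adjusted p = 0.000692, adjusted p = 0.615 with an estimated correlation). CYCB1;2, a mitotic cyclin, fell from 1928 ± 138 to 867 ± 240.4 (log2 fold change -1.19, adjusted p = 0.00504), and HINKEL, a kinesin of the cell plate, from 1363 ± 131 to 612 ± 155 (log2 fold change -1.18, adjusted p = 0.00497). In these 3 lists, and in some that did not pass, library means at 5 d and 0 d did not overlap. 1 of 11 histone genes rose and 2 fell (lowest 1, 1 and 4 adjusted over the list alone, median log2 fold change -0.41, camera adjusted p = 0.0971).

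4 of 5 sugar starvation genes rose and none fell (lowest 1, median log2 fold change 0.64, camera adjusted p = 0.45). BZIP1 was the 1 call left without V2 0 d replicate 3 or V2 5 d replicate 2. 1 of 9 BRC1 and dormancy genes rose and 1 fell (lowest 1, median log2 fold change -0.25, camera adjusted p = 0.53). 2 of 8 abscisic acid response genes rose and none fell (lowest 1, median 0.58, camera adjusted p = 0.778). BZIP1 rose from 184 ± 25.4 to 413 ± 24.2 (log2 fold change 1.17, adjusted p = 0.00811), and ABI1 from 858 ± 148 to 2591 ± 187 (log2 fold change 1.61, adjusted p = 0.000294). HB40, of the group downstream of BRC1, fell from 271 ± 87.6 to 106 ± 18.3 (log2 fold change -1.30, adjusted p = 0.00762). NCED3, the 1 metabolism gene, was not called (log2 fold change 0.54, adjusted p = 0.563). 2 of 7 gibberellin genes rose and none fell (lowest 0, median log2 fold change 0.59, camera adjusted p = 0.728). None of 5 cytokinin metabolism genes was called (median 0.15, mean -0.11, test direction lower, camera adjusted p = 0.778). 1 of 3 auxin synthesis and transport genes rose and none fell (lowest 0, median 0.40, camera adjusted p = 0.532). 2 of 5 auxin response genes rose and none fell (lowest 0, 3 and 1 adjusted over the list alone, median 1.64, camera adjusted p = 0.778). ARR4 was not called (log2 fold change -0.60). IAA14, an auxin-inducible repressor, rose from 5.41 ± 1.97 (n = 2) to 60.4 ± 13.4 (log2 fold change 3.27, adjusted p = 0.0158).

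HSFA2, a heat shock factor and the 1 member of its list tested (lowest 0), fell from 6204 ± 2957 (n = 2) to 254 ± 134 (log2 fold change -4.67, adjusted p = 0.000823). Outside the list, its relative HSFA7A was listed at 0 at 5 d and had 629.98, 1270 and 1409 (adjusted p = 7.59e-07) at 0 d, and the mitochondrial small heat shock gene HSP23.6-MITO fell from 2503 ± 257 to 10.6 ± 12.1 (log2 fold change -8.69, adjusted p = 0.00131). 2 of 7 cold response genes rose and 1 fell (lowest 2, median log2 fold change 0.28, mean 0.37, test direction lower, camera adjusted p = 0.927). 1 of 6 clock genes rose and none fell (median 0.23, camera adjusted p = 0.778). 1 of 6 meristem and boundary genes rose and 2 fell (lowest 1, median -0.17, camera adjusted p = 0.53). BAM3, a plastid beta-amylase, rose from 1664 ± 812 to 5982 ± 883 (log2 fold change 1.96, adjusted p = 0.00364), while GOLS3 fell from 654 ± 154 to 182 ± 30.9 (log2 fold change -1.83, adjusted p = 0.00928). PRR5, a clock repressor, rose from 782 ± 224 to 2186 ± 197 (log2 fold change 1.52, adjusted p = 0.00631), and CUC1, an organ boundary gene, fell from 342 ± 18.6 to 158 ± 28 (log2 fold change -1.12, adjusted p = 0.00361). None of 3 flowering repressors was called (median log2 fold change 0.40, camera adjusted p = 0.811). 1 of 4 flowering promoters fell and none rose (lowest 0, 0 and 2 adjusted over the list alone, median -0.48, camera adjusted p = 0.53). Of the 2 floral organ identity genes (lowest 0), CRC fell from 84.4 ± 29.7 (n = 2) to 2.71 ± 2.4 (log2 fold change -4.81, adjusted p = 0.00227) and UFO was not called (log2 fold change -0.06).

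3 of 8 wall loosening genes rose and 2 fell (lowest 3, median log2 fold change 0.11, mean 0.40, test direction lower, camera adjusted p = 0.778). 3 of 5 jasmonate and defence genes rose and none fell (lowest 1, 4 and 1 adjusted over the list alone, median 0.72, camera adjusted p = 0.53). 2 of 5 flavonoid genes rose and none fell (median 0.55, mean -0.74, test direction higher, camera adjusted p = 0.778). XTH6, a xyloglucan endotransglucosylase, rose from 291 ± 10.9 to 1404 ± 132 (log2 fold change 2.27, adjusted p = 0.0119), and its relative XTH8 fell from 414 ± 12.7 to 147 ± 50.1 (log2 fold change -1.54, adjusted p = 0.00106). LOX2 rose from 346 ± 45.1 to 4747 ± 1923 (log2 fold change 3.68, adjusted p = 0.000385), and CHS, the entry enzyme of flavonoid synthesis, from 1949 ± 496 to 5148 ± 1873 (log2 fold change 1.36, adjusted p = 0.0074). 2 of 4 vascular markers rose and none fell (lowest 1, 3 and 0 adjusted over the list alone, median log2 fold change 3.96, camera adjusted p = 0.174). 1 of 3 photosynthetic markers rose and none fell (2 and 0 adjusted over the list alone, median 0.41, camera adjusted p = 0.728). 1 of 2 senescing-leaf markers rose and none fell. XCP1 was listed at 0 at 0 d and had 109, 78.2 and 27.8 (adjusted p = 4.66e-06) at 5 d, and CA1, a carbonic anhydrase, rose from 60.6 ± 12.9 to 1098 ± 658 (log2 fold change 3.94, adjusted p = 0.00187). Among genes of no list, BAM5, a beta-amylase, was listed at 0 at 0 d and had 257, 184 and 221 (adjusted p = 1.61e-08) at 5 d.

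The number called by limma was 2075 without V2 0 d replicate 2, and 2283 and 2574 without V2 5 d replicates 1 and 2. Of the 58 named calls, 14, 24 and 15 ended without V2 0 d replicates 1, 2 and 3, and 22, 18 and 11 without V2 5 d replicates 1, 2 and 3.

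The growing-zone buds were compared between the same days to ask what changes as they grow. Of 17197 genes tested, limma called 4171, with 2296 rising and 1875 falling, and 1978 changed at least 2-fold. By camera the meristem and boundary, clock, sugar starvation, dormancy and ribosomal protein lists fell. With an estimated correlation the meristem and boundary list alone passed (adjusted p = 0.0134, the others 0.143 to 0.426). Most jasmonate, flavonoid and vascular genes measured were called as rising, although none of these lists passed camera, and no S phase or G2/M gene was called.

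Of the 6 meristem and boundary genes, 6 fell and none rose (lowest 4, median log2 fold change -1.37, camera adjusted p = 0.00166, adjusted p = 0.0134 with an estimated correlation). CUC1 fell from 309 ± 67.9 to 56 ± 3.6 (log2 fold change -2.42, adjusted p = 2.71e-05), KNAT6, a boundary homeobox gene, from 398 ± 12.2 to 178 ± 40.4 (log2 fold change -1.18, adjusted p = 0.00128), and RAX1, a MYB gene of axillary meristems, from 25.9 ± 6.69 to 10.2 ± 2.94 (log2 fold change -1.27, adjusted p = 0.00939). Of the 5 clock genes, 5 fell and none rose (lowest 2, median log2 fold change -2.77, camera adjusted p = 0.00954, adjusted p = 0.143 with an estimated correlation). ELF4 fell from 148 ± 36.8 to 10.7 ± 6.37 (log2 fold change -3.76, adjusted p = 0.000389), and BOA, of the evening complex, from 178 ± 80.5 to 25.6 ± 15.3 (log2 fold change -2.77, adjusted p = 0.00624). Both flowering repressors fell, TFL1 from 3320.4 ± 580.1 to 444 ± 76.1 (log2 fold change -2.90, adjusted p = 3e-06) and SVP from 2929.7 ± 592 to 2028 ± 299.9 (log2 fold change -0.52, adjusted p = 0.0461, but up to 0.153 without 4 single libraries in turn). 1 of 4 flowering promoters rose and 2 fell (lowest 2, median log2 fold change -0.33, camera adjusted p = 0.551). SPL3, which promotes flowering with age, rose from 48.5 ± 22.5 to 152 ± 15 (log2 fold change 1.72, adjusted p = 0.00984). Of the 2 floral organ identity genes, UFO fell from 321 ± 41.6 to 70.9 ± 22 (log2 fold change -2.21, adjusted p = 0.000211) and CRC was not called (log2 fold change -1.20).

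Of the 9 BRC1 and dormancy genes, 1 rose and 4 fell, with 4 not called (lowest 4, 1 and 5 adjusted over the list alone, median log2 fold change -1.51, camera adjusted p = 0.0197, adjusted p = 0.362 with an estimated correlation). That list's adjusted p was 0.0672 without V3 0 d replicate 2. DRMH1 fell from 4465 ± 3229 to 70.9 ± 47.8 (log2 fold change -5.76, adjusted p = 0.0014), HB53 from 886 ± 660.1 to 85.6 ± 9.42 (log2 fold change -3.05, adjusted p = 0.00251), and the drought-induced NAC gene ATAF1 from 869 ± 148 to 263 ± 94.4 (log2 fold change -1.77, adjusted p = 0.00193). The member that rose was HIS1-3, which is also the 1 histone gene called (log2 fold change 2.19, adjusted p = 0.0334, but up to 0.0951 without 5 single libraries in turn). NCED3, the 1 metabolism gene, was not called (log2 fold change -0.52, adjusted p = 0.599). Of the 4 sugar starvation genes, 4 fell and none rose (lowest 3, median log2 fold change -1.14, camera adjusted p = 0.0105, adjusted p = 0.292 with an estimated correlation). TPS9 fell from 2926 ± 382 to 1052 ± 182 (log2 fold change -1.48, adjusted p = 0.000163), and BZIP1 from 117 ± 33.3 to 50.8 ± 12.1 (log2 fold change -1.17, adjusted p = 0.00686). 1 of 8 abscisic acid response genes rose and 2 fell (median log2 fold change -0.57, camera adjusted p = 0.226). 2 of 7 cold response genes fell and none rose (lowest 1, 1 and 2 adjusted over the list alone, median -0.39, camera adjusted p = 0.0738). ABI5 fell from 404 ± 56.7 to 32 ± 16.8 (log2 fold change -3.77, adjusted p = 0.000212) and COR28 from 167 ± 35.6 to 7.23 ± 4.93 (n = 2) (log2 fold change -4.47, adjusted p = 0.000185), whereas RD22, a drought-induced wall protein, rose from 712 ± 242 to 2945 ± 1338 (log2 fold change 2.01, adjusted p = 0.00233). Both heat shock genes fell, HSP18.2 from 353 ± 128 to 14.8 ± 4.09 (log2 fold change -4.45, adjusted p = 0.000222).

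Of the 30 ribosomal protein genes, 1 rose and 7 fell, with 22 not called (lowest 4, 1 and 11 adjusted over the list alone, median log2 fold change -0.47, camera adjusted p = 0.000816, adjusted p = 0.426 with an estimated correlation). In the 5 lists that passed camera, library means at 5 d lay below those at 0 d (2 of 3 in sugar starvation). Some lists that did not pass were as separate. None of 9 S phase genes was called (median log2 fold change -0.02, mean 0.08, test direction lower, camera adjusted p = 0.555). None of 12 G2/M genes was called (median 0.06, mean 0.03, test direction lower, camera adjusted p = 0.579). 1 of 10 histone genes rose and none fell (lowest 0, 0 and 0 adjusted over the list alone, median 0.10, mean 0.23, test direction lower, camera adjusted p = 0.796). 2 of 3 auxin synthesis and transport genes rose and none fell (3 and 0 adjusted over the list alone, median log2 fold change 1.43, camera adjusted p = 0.127). 3 of 4 auxin response genes rose and 1 fell (lowest 3, median 3.299, camera adjusted p = 0.827). 1 of 4 cytokinin metabolism genes fell and none rose (lowest 0, 1 and 2 adjusted over the list alone, median -0.75, camera adjusted p = 0.361). 1 of 7 gibberellin genes rose and 1 fell (lowest 1, 1 and 2 adjusted over the list alone, median -0.62, camera adjusted p = 0.189). PIN7, an auxin carrier, rose from 131 ± 63.6 to 329.6 ± 49.2 (log2 fold change 1.43, adjusted p = 0.0133), and IAA14 from 3.26 ± 4.6 (n = 2) to 126 ± 9.52 (log2 fold change 5.53, adjusted p = 0.00163), while GH3.6 fell from 11457 ± 479.6 to 3049 ± 188 (log2 fold change -1.91, adjusted p = 1.21e-06). ARR4, the 1 type-A regulator, rose from 442 ± 104 to 918 ± 15.7 (log2 fold change 1.08, adjusted p = 0.03, but up to 0.0835 without 5 single libraries in turn). RGL1 rose from 63.8 ± 9.33 to 149 ± 15.6 (log2 fold change 1.22, adjusted p = 0.00142), and GA20OX2, a late enzyme of gibberellin synthesis, was listed at 0 at 5 d with 38.4 and 54.9 (adjusted p = 1.44e-06) at 0 d.

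4 of 5 jasmonate and defence genes rose and none fell (lowest 3, median log2 fold change 1.78, camera adjusted p = 0.117). 3 of 4 flavonoid genes rose and none fell (lowest 2, median 1.41, camera adjusted p = 0.246). 3 of 8 wall loosening genes rose and 1 fell (lowest 3, 5 and 1 adjusted over the list alone, median 1.90, camera adjusted p = 0.507). LOX2 rose from 1829.7 ± 1168 (n = 2) to 61436 ± 5706 (log2 fold change 5.23, adjusted p = 9.69e-05), and AOS, the next enzyme of that pathway, from 826 ± 88.3 to 2962 ± 1139 (log2 fold change 1.78, adjusted p = 0.00187). CHS rose from 1151 ± 103 to 6364 ± 706 (log2 fold change 2.46, adjusted p = 0.000269), XTH6 from 339 ± 220.1 to 2903 ± 465 (log2 fold change 3.42, adjusted p = 0.00147), and EXPA10 from 627 ± 258 to 2879 ± 174 (log2 fold change 2.29, adjusted p = 0.000269). 3 of 3 vascular markers rose and none fell (median log2 fold change 6.22, camera adjusted p = 0.0722). 1 of 4 photosynthetic markers rose and none fell (median 0.67, camera adjusted p = 0.379). 1 of 2 senescing-leaf markers rose and none fell. XCP2, a vessel protease, rose from 3.84 ± 6.65 to 173 ± 14.4 (log2 fold change 6.22, adjusted p = 0.00115). Outside the lists, the galactinol synthase GolS1 and PLC1 were listed at 0 in usable libraries at 0 d. At 5 d they had 725, 901 and 1165 (adjusted p = 0.000808) and 892, 941 and 996 (adjusted p = 8.34e-07). HSFA7A fell from 1590.4 ± 786 to 0.704 ± 1.22 (log2 fold change -9.95, adjusted p = 1.68e-06).

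Of the 68 named calls in V3, 8, 8 and 15 ended without V3 0 d replicates 1, 2 and 3, and 10, 10 and 9 without V3 5 d replicates 1, 2 and 3. Of the genes tested in both zones, 906 rose in V2 and in V3, where independence would give 266.4, and 598 fell in both, where it would give 201.2. Another 113 were called in opposite directions, and the changes of all genes correlated at r = 0.485. The 1504 genes shared became 880 and 988 without V2 0 d replicate 2 and V2 5 d replicate 1.

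The interaction asked which genes changed differently between the zones over the 5 days. A gene whose change was more positive in V3 is given as relatively higher, and its fold change is the difference of both changes. Of 16039 genes tested, limma called 1124, 641 relatively higher and 483 relatively lower, and 698 had a difference of at least 2-fold. With zeros as deposited limma called 339 relatively higher and 425 relatively lower. By camera the sugar starvation, clock and meristem and boundary lists were relatively lower in growing-zone buds, as were 4 others, and all were lost with an estimated correlation (lowest adjusted p = 0.0646). In sugar starvation genes the mean values went up in V2 and down in V3, while TFL1 and UFO fell in V3 and were not called in V2.

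Of the 4 sugar starvation genes, 4 were relatively lower in V3 and none was relatively higher (median log2 fold change -2.08, camera adjusted p = 0.00155, adjusted p = 0.137 with an estimated correlation). TPS9 went from 3305 ± 402 to 5142 ± 680.3 in V2 and from 2926 ± 382 to 1052 ± 182 in V3 (log2 fold change -2.12, adjusted p = 0.000189). KMD4, an F-box gene that targets cytokinin response regulators, went from 3133 ± 667 to 5965 ± 1071 in V2 and from 2051 ± 709 to 936 ± 250.3 in V3 (log2 fold change -2.04, adjusted p = 0.0124). The differences were -2.34 (adjusted p = 0.0028) in BZIP1 and -1.49 (adjusted p = 0.00669) in TPS11, a relative of TPS9. Of the 5 clock genes, 2 were relatively lower in V3 and none was relatively higher, with 3 not called (0 and 5 adjusted over the list alone, median log2 fold change -2.77, camera adjusted p = 0.00406, adjusted p = 0.0646 with an estimated correlation). PRR5 went from 782 ± 224 to 2186 ± 197 in V2 and from 637 ± 113 to 329.6 ± 153 in V3 (log2 fold change -2.54, adjusted p = 0.00484), and ELF4 differed by -3.98 (adjusted p = 0.00425). FKF1 and BOA were not called at -5.26 and -2.77. Of the 6 meristem and boundary genes, 3 were relatively lower in V3 and none was relatively higher, with 3 not called (lowest 2, 0 and 4 adjusted over the list alone, median log2 fold change -1.28, camera adjusted p = 0.00815, adjusted p = 0.0646 with an estimated correlation). RAX2 went from 68.6 ± 13.7 to 179 ± 42.9 in V2 and from 54.9 ± 22.6 to 18.4 ± 5.87 in V3 (log2 fold change -2.84, adjusted p = 0.0122), and KNAT6 differed by -1.26 (adjusted p = 0.0161). Both flowering repressors were relatively lower, SVP with a call that ended without any of 9 single libraries. TFL1 went from 3024 ± 465 to 2769 ± 236 in V2 and from 3320.4 ± 580.1 to 444 ± 76.1 in V3 (log2 fold change -2.78, adjusted p = 3.81e-05). Of the 2 floral organ identity genes, UFO went from 329.9 ± 36.1 to 316 ± 43.4 in V2 and from 321 ± 41.6 to 70.9 ± 22 in V3 (log2 fold change -2.14, adjusted p = 0.00438), and CRC was not called (log2 fold change 3.62, relatively higher when adjusted over the list alone). These 3 list calls held without each library.

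Of the 9 BRC1 and dormancy genes, 2 were relatively lower in V3 and none was relatively higher, with 7 not called (lowest 0, 0 and 3 adjusted over the list alone, median log2 fold change -1.06, camera adjusted p = 0.0425, adjusted p = 0.435 with an estimated correlation). Its adjusted p was at most 0.0957 and missed 0.05 without 7 single libraries in turn. Of the 8 abscisic acid response genes, 2 were relatively lower in V3 and none was relatively higher, with 6 not called (lowest 1, 0 and 3 adjusted over the list alone, median log2 fold change -1.10, camera adjusted p = 0.045, adjusted p = 0.435 with an estimated correlation). Its adjusted p was at most 0.125 and missed 0.05 without 7 single libraries in turn. ABI1 went from 858 ± 148 to 2591 ± 187 in V2 and from 409 ± 107 to 429 ± 30.7 in V3 (log2 fold change -1.51, adjusted p = 0.00636). NCED3, the 1 metabolism gene, was not called (log2 fold change -1.06, adjusted p = 0.492). Of the 7 cold response genes, 2 were relatively lower in V3 and none was relatively higher, with 5 not called (lowest 1, median log2 fold change -1.52, camera adjusted p = 0.00866, adjusted p = 0.284 with an estimated correlation). Its adjusted p was 0.0957 and 0.0736 without V3 0 d replicates 2 and 3. COR28 went from 198 ± 59.9 to 161 ± 37.6 in V2 and from 167 ± 35.6 to 7.23 ± 4.93 (n = 2) in V3 (log2 fold change -4.19, adjusted p = 0.00255). Of the 7 gibberellin genes, 1 was relatively higher in V3 and 1 relatively lower, with 5 not called (lowest 1, 1 and 5 adjusted over the list alone, median log2 fold change -1.22, camera adjusted p = 0.0402, adjusted p = 0.284 with an estimated correlation). Its adjusted p was at most 0.167 and missed 0.05 without 6 single libraries in turn. Of the 12 G2/M genes, 2 were relatively higher in V3 and none was relatively lower, with 10 not called (lowest 0, 7 and 0 adjusted over the list alone, median log2 fold change 1.01, camera adjusted p = 0.0317, adjusted p = 0.435 with an estimated correlation). Its adjusted p was at most 0.0957 and missed 0.05 without 4 single libraries in turn.

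None of 9 S phase genes was called (2 and 0 adjusted over the list alone, median log2 fold change 0.66, camera adjusted p = 0.118). None of 10 histone genes was called (median 0.58, camera adjusted p = 0.199). 2 of 30 ribosomal protein genes were relatively higher in V3 and none relatively lower (lowest 0, 4 and 0 adjusted over the list alone, median 0.46, camera adjusted p = 0.118). None of 3 auxin synthesis and transport genes was called (1 and 0 adjusted over the list alone, median log2 fold change 1.11, camera adjusted p = 0.325). 1 of 4 auxin response genes was relatively lower and none relatively higher (1 and 1 adjusted over the list alone, median 1.31, mean 0.82, test direction lower, camera adjusted p = 0.882). None of 4 cytokinin metabolism genes was called (median -0.53, camera adjusted p = 0.572). GH3.6 went from 12333 ± 1321 to 9959 ± 845 in V2 and from 11457 ± 479.6 to 3049 ± 188 in V3 (log2 fold change -1.60, adjusted p = 7.02e-05). ARR4, the 1 type-A regulator, was relatively higher by 1.68 (adjusted p = 0.0394, but up to 0.0836 without 9 single libraries in turn). None of 4 flowering promoters was called (median log2 fold change 0.16, camera adjusted p = 0.897). 1 of 5 jasmonate and defence genes was relatively higher in V3 and none relatively lower (3 and 0 adjusted over the list alone, median 1.06, camera adjusted p = 0.145). None of 8 wall loosening genes was called (2 and 0 adjusted over the list alone, median 1.26, camera adjusted p = 0.123). JAZ10 went from 1007 ± 129 to 1591 ± 342 in V2 and from 431 ± 88.1 to 1715 ± 245 in V3 (log2 fold change 1.35, adjusted p = 0.0166). None of 4 flavonoid genes was called (2 and 0 adjusted over the list alone, median log2 fold change 0.95, camera adjusted p = 0.256). None of 3 vascular markers was called (1 and 0 adjusted over the list alone, median 1.88, camera adjusted p = 0.429). 1 of 2 photosynthetic markers was relatively higher in V3 and none relatively lower (lowest 0). None of 2 senescing-leaf markers was called. The 1 heat shock gene tested was not called.

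Among genes of no list, ATSDI1 had 2616, 1409.9 and 2889 in V3 at 5 d and KAT2 had 602, 609 and 719.8, and both were listed at 0 in the other 3 groups (adjusted p = 2.5e-06 for each). DREB2A went from 780.4 ± 258 to 695 ± 138 in V2 and from 515 ± 42.3 to 12.2 ± 9.97 in V3 (log2 fold change -5.45, adjusted p = 0.000862). Without single libraries limma called 638 (V3 5 d replicate 2) to 1903 (V3 0 d replicate 1). Of the 35 named calls, 2 to 14 ended without a single library, and 13 held in every alternative that tested them.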

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

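The tests of library depth and of absent transcript, both tests of large log2 fold changes and the test of values lost in 1 library in genes without a failed zero were chosen after the result was seen, and the remaining tests before.

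What singled out each value here is that the change over time differed between the zones. The interaction called 1124 genes. Among the named genes its adjusted p was 2.5e-06 for ATSDI1 and 2.5e-06 for KAT2, 0.0492 for GGCT2;1, 6.12e-06 for PLC1, 0.000123 for ABCG21 and 0.000285 for GOLS3. It was 0.000862 for DREB2A, 0.047 for DRMH1, 0.0147 for MEE14 and 0.00255 for COR28. The adjusted p of DRMH1 and GGCT2;1 missed 0.05 without 8 and 5 single libraries in turn (up to 0.0979 and 0.105). Among the lists it was 0.0425 for dormancy, 0.00155 for sugar starvation, 0.045 for abscisic acid response, 0.0402 for gibberellin, 0.0317 for G2/M, 0.00815 for meristem and boundary, 0.00866 for cold response and 0.00406 for the clock. With an estimated correlation none of these lists passed. When the zone labels were exchanged within each time, 6 of 100 draws called as many genes, 1 of them the real labels and 5 exchanged ones, the highest with 6208, because such draws can carry the zone difference of 5 d into the interaction. The count of 1124 is therefore not separated from the structure of the samples by that test, and 1 of 10 splits reached the real count in each pair of groups (722, 6232, 3956 and 4171, the highest other splits 23, 7, 6 and 5), too few splits for a share under 0.05.

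V2 replicate 3 at the end of the cold held 6553 failed zeros. Lower depth is argued against, because 37.3% of genes with at least 200 counts in both partners stood at 0 there (4454 of 11933) and 0.906% to 1.46% in the other libraries. Absent transcript is argued against as well, since 87.6% of its zeros where a partner held at least 20, in genes with FPKM, had an FPKM of at least 1 (290 of 331). Loss of counts between alignment and the count table stays open and could explain them, as 90.9% of these FPKM lay within 2-fold of the partners (301 of 331). That test covers listed genes alone.

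The authors' 4 tables hold 1476 entries with an absolute log2 fold change of at least 10 and FPKM in both groups, a gene counting once per table. Zeros that are not absence of transcript may account for most of them, since 81.4% differed less than 2-fold in FPKM. Genes that switch on or off fit few, as 7.79% differed at least 8-fold. Which step wrote the zeros was not tested.

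More genes differed between the zones at 5 d (6232) than at the end of the cold (722). A larger spread between replicates at 0 d and a larger zone difference at 5 d are both left open: the spread-corrected SD of zone differences was 1.43 times as large at 5 d, 1.22 at the lowest and 1.66 at the highest with 1 library left out. Values lost in V2 replicate 3 are argued against, for genes without a failed zero in any library, where the count at 5 d was 6.04 times that at 0 d (4070 against 674). For genes with a failed zero in that library they stay open, since the ratio of calls was 1.64 times that of genes without one (1624 to 117 against 3929 to 463).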

How the results depend on the processing

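Alternatives fixed before the data were examined were the threshold, DESeq2, limma-voom for the interaction, the filters, RLE factors, the groups compared only, the replicate block, fry, the estimated correlation and the libraries left out in turn; those on zeros, FPKM, scaling, the pseudocount and the 2 libraries that stand apart were chosen after seeing the data. limma-voom, edgeR and DESeq2 ran on genes without a failed zero except where zeros as deposited are named, and FPKM covers 3877 listed genes, so with these the gene set changed as well. The planned edgeR test with TMM on raw counts was not run as planned because the files hold normalized counts. The cause of a difference was not tested. Counts of called genes not mentioned stayed within 1.5-fold.

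Between zones at 0 d, 722 genes became 458 with at least 2-fold change, 333 with a replicate block, 187 with the groups compared only, 1627 with DESeq2 on genes without a failed zero, 1271 with FPKM, 394 and 2120 with zeros as deposited in edgeR and DESeq2, 234 without the 2 libraries that stand apart, and 191 to 1745 without single libraries. At 5 d, 6232 became 2527 at 2-fold, 4053, 4070 and 4152 with edgeR, limma and limma-voom on genes without a failed zero, 3131 and 2760 with zeros as deposited in limma and edgeR, and 2634 with FPKM. With zeros as deposited, edgeR's calls were 63.5% higher in V3 at 0 d against 25.8% above, 58.1% against 45% at 5 d, 64.6% rising against 55% in V3, and 36.6% against 57% for the interaction. In V2, 3956 became 1549 at 2-fold, 2140 and 1705 with zeros as deposited in limma and edgeR, 2120 with FPKM, and 2075 to 3233 without single libraries. In V3, 4171 became 1978 at 2-fold, 2774, 2775 and 2725 with edgeR, limma and limma-voom on genes without a failed zero, 2052 and 1583 with zeros as deposited in limma and edgeR, and 2137 with FPKM. For the interaction, 1124 became 698 at 2-fold, 673 with edgeR, 727 with limma-voom, 516 and 2022 with zeros as deposited in edgeR and DESeq2, 728 with a replicate block, 1716 without the 2 libraries and 638 to 1903 without single libraries.

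Libraries of the same replicate number did not resemble each other across groups (r from -0.135 to 0.102, against -0.186 to 0.206 for other numbers), so the block had no measured pairing behind it. Of the lists, 5, 10, 3, 5 and 8 passed camera in the comparisons in order; with an estimated correlation 0, 0, 0, 1 and 0 did, and with fry 10, 17, 9, 13 and 9. At 0 d, zeros as deposited gave 3 lists with limma and 0 with DESeq2. In V2, DESeq2 gave 2 with either treatment of zeros, FPKM gave 5, and single libraries 3 to 5. For the interaction, genes without a failed zero gave 3 with DESeq2 and 4 with each of edgeR, limma and limma-voom, zeros as deposited gave 5, 4 and 0 with limma, edgeR and DESeq2, and single libraries 3 to 12. The 1504 genes shared over time became 632 at 2-fold and 880 to 1703 without single libraries. The 387 shared between zones became 179 at 2-fold, 1114 with DESeq2 on genes without a failed zero, 151 with the block, 87 without the 2 libraries, 1069 with zeros as deposited in DESeq2, and 91 to 1124 without single libraries. With zeros as deposited in DESeq2, the correlation r was 0.103 against 0.338 between zone differences and 0.209 against 0.485 between changes over time, and opposite calls were 108 against 19 and 180 against 113.

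Of the authors' listed genes, 258 called here at 0 d became 1124 and 455 with zeros as deposited in DESeq2 and limma, 475 with DESeq2 on genes without a failed zero and 506 with FPKM, and 935 in V2 became 1750 with zeros as deposited in DESeq2. LOX2 turned direction between zones at 0 d with zeros as deposited in limma, to a log2 fold change of -1.31 (adjusted p = 0.733), and kept its direction elsewhere. Of the named calls, 2 of 30, 57 of 78, 28 of 58, 41 of 68 and 13 of 35 held in every alternative that tested them.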

Other observations

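Gene families read from the annotation text added groups that the fixed lists did not hold, and 8 of 22 families tested passed Fisher's exact test in at least 1 comparison (14 of 220 tests), 7 of them as called more often than other genes. Kinesins followed the zones: at 5 d 13 of 14 (92.9% against 28.6% of the other genes with a homologue, Fisher exact adjusted p = 8.9e-05) were higher in V3, at 0 d 7 of 13 against 76 of 2401 other genes (adjusted p = 7.83e-06), and in V2 10 of 13 against 421 of 2421 other genes (adjusted p = 0.00022) fell over the 5 days. At 5 d the log2 fold change was 1.38 for POK2, which places the division plane, and 2.40 for KIN-1. Lower in V3 at 5 d, against 887 of 2541 other genes, were 12 of 12 WRKY genes (adjusted p = 0.00022) and 15 of 18 NAC genes (adjusted p = 0.0012), among them WRKY18 (-3.02), WRKY15 (-2.06), NAC060 (-5.78) and NAC089 (-2.34). AP2/ERF genes were higher in V3 less often than others, 2 of 42 against 726 of 2541 (adjusted p = 0.00466). The NAC family shares NAP, ATAF1 and CUC3 with the lists, and HINKEL is a kinesin of the G2/M list.

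Glucosinolate genes rose in growing-zone buds over the 5 days, 13 of 15 against 886 of 2498 other genes (adjusted p = 0.00199). They included MYB34, an activator of indole glucosinolate synthesis (1.82), the synthesis enzymes CYP83B1 (2.12) and SOT16 (4.90), the transporter NPF2.10 (1.38) and the myrosinase TGG2 (2.85). Of pectin methylesterases and their inhibitors 17 of 24 against 886 of 2498 (adjusted p = 0.0099) rose and 3 fell, with the enzyme PME61 at 4.12 and the inhibitor ATPMEI10 at 5.65. Nucleolar genes of ribosome assembly fell in both zones, in V2 10 of 15 against 421 of 2421 other genes (adjusted p = 0.0012) and in V3 9 of 15 against 382 of 2498 (adjusted p = 0.00244), and FIB2 fell by 1.05 and 1.32. Small heat shock genes were split in V2, where 5 of 7 against 421 of 2421 other genes (adjusted p = 0.0407) fell and the other 2 rose, and 4 of 7 fell in V3 (adjusted p = 0.141). All families rest on genes the authors had listed as changed, so shares are not independent of these libraries.

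HSFA7A was lower at 5 d than at the end of the cold in both zones, which may follow the change of temperature or the time of harvest; with each alternative that kept all libraries it stayed called in both zones, but neither cause was tested. No hour of harvest is given in the sources used here, and the clock genes ELF4 and BOA differed between zones at the same 5 d. The vascular markers averaged more at 5 d than at 0 d in every library, but between zones at 5 d they did not pass camera (adjusted p = 0.193), and FLA11, 1 of their 2 calls, lost its call in 5 of the 6 fits without a single library. More vascular tissue in the V3 samples is therefore left open. A spread-corrected ratio of 1.43 between the zone differences at 5 d and at 0 d does not separate tissue share from regulation.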
